A study of Mus musculus with 20 samples.

How the data were processed

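Messenger and other RNA was measured by bulk RNA sequencing of sorted mouse skin cells. Per the labels, the knockout and tumour-bearing mice carried the K14cre transgene, which expresses Cre recombinase in keratinocytes. They had floxed alleles of Wwox, of Trp53 (p53) or of both, and the titles of the control samples read only wild type. Cells positive for the tdTomato reporter were sorted, per the labels, from dissociated epidermis or from cutaneous squamous cell carcinomas (cSCC) that arose spontaneously. Young epidermis came from mice 100 to 120 days old and old epidermis from mice of 400 days or more, per the labels, which give no age for the tumour-bearing mice. Libraries were made from 5 ng of RNA with a stranded total RNA kit for low input that adds molecular identifiers. Whether those identifiers were used in counting is not given in the sources used here.

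The submitters' processing notes name Trim Galore 0.4.1, FastQC 0.11.5, Salmon 0.13.1, DESeq2 1.28.1 and the mouse build mm39, with no role or order. The authors deposited 1 table of estimated counts (expected counts) for 51123 Ensembl gene identifiers in 20 libraries, already whole numbers. All 37 values of 7 or more digits were multiples of 10, so the largest values had been rounded before deposit. How transcript estimates were summed to genes, and which annotation release was used, is not given in the sources used here. Reads shared by near-identical copies were split by that estimation, so levels of ribosomal protein genes, pseudogenes, histone, globin, keratin and casein family members carry that uncertainty. A symbol was found for 48246 identifiers in a GENCODE annotation of another build (GRCm38), which served for names only, and no coordinates are given. Identifiers with no symbol took 3.74% to 12% of the counts of a library and stayed in the tests.

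From these counts edgeR 4.0.16 (R 4.3.3) was run with trimmed mean of M-values (TMM) scaling, filterByExpr at its defaults, and the quasi-likelihood F test, with Benjamini-Hochberg adjustment at 0.05. Comparisons within young epidermis shared a fit of 12 libraries (16627 genes), tumour comparisons a fit of 8 libraries that included old WT epidermis (16526 genes), old against young WT a fit of 14 (17622 genes), and the test of tissue against genotype a fit of all 20 (18164 genes). The quasi-likelihood fit estimates 1 prior for all genes. Levels are counts scaled by library size (CPM) after TMM scaling of all 20 libraries, given as mean ± SD. Log2 fold changes are from the fit, with the standard error (SE).

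Before the data were examined, 30 gene lists were fixed: 22 of pathways and skin cell states, such as EMT transcription factors, mesenchymal genes of the epithelial to mesenchymal transition (EMT), epithelial junction genes and p53 targets, and 8 of markers of cell types that a skin sort could also hold. Each was tested with camera (limma 3.58.1) on voom values with a preset correlation of 0.01, and again with an estimated correlation and with fry. Fry asks whether the genes of a list move, on balance, one way, and does not compare them with other genes. Counts of list members were also taken with p-values adjusted over the list alone.

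Genes were named by a rule fixed at the same time. Among genes with an official symbol, outside predicted, immunoglobulin, T cell receptor, mitochondrial, ribosomal protein and small RNA genes, it took those past the threshold with no overlap of the groups' libraries and at least 5 CPM in the higher group, and named the 10 largest changes each way. Chance gives no overlap for 10% of genes in groups of 3 against 3. Where fewer than 5 genes passed, the 5 such genes with the smallest p were named as values. Overlap could not be judged for differences of effects, where the rule used p alone. Up to 4 members of a list with the smallest p were added, with Wwox and Trp53 always.

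Alternatives were the replicate number as a block, relative log expression (RLE) and TMMwsp scaling, no low-count filter, a minimum of 10 CPM, DESeq2 1.42.0, limma voom with quality weights, other sets of libraries in the fit, other controls for the tumours, a test against a log2 change of 1, and each library left out in turn. Added after seeing the data were a robust prior, removal of doubted libraries, a T cell marker score as a covariate, and an adjusted p under 0.1.

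The edgeR step was tested on a single simulated data set for each comparison, with 200 genes changed. The shares below therefore carry the variation of a single draw, and gaps between comparisons may come from it. At a log2 change of 3 it found 34.8% of the changed genes for DKO against PKO cSCC, 1.52% for PKO cSCC against old WT, 18.2% for DKO cSCC against old WT and 65.2% for WKO against WT young epidermis. At a log2 change of 2 the shares were 2.99%, 0%, 1.49% and 56.7%. None of the recovered genes had the wrong sign in any of the 10 simulations. Unchanged genes made up 8 of 92 calls for WKO and 4 of 80 for PKO against WT young, and 1 of 14 for DKO cSCC against old WT. The other simulations had at most 3 such calls. The share found depends on how many genes change, so these shares need not hold where more than 200 genes differ. Library totals lay between 11930153 and 17199262 counts, and intervals from counts cover counting error only.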

Results

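RNA was profiled in tdTomato-positive cells of mouse skin in 7 groups. Young epidermis was wild type (WT, n = 3), deleted for Wwox (WKO, n = 3), for p53 (PKO, n = 3) or for both (DKO, n = 3), and was set beside old WT epidermis (n = 2) and carcinomas from PKO (n = 3) and DKO (n = 3) mice. The labels call the samples of a group biological replicates. Total counts ranged from 11930153 (WKO young 1) to 17199262 (DKO young 2). Mitochondrial ribosomal RNA took 15% (WKO young 1) to 40.9% (the library labelled DKO cSCC 3) of the counts, and 18682 to 25735 genes had at least 1 count.

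Wwox (ENSMUSG00000004637), which encodes a WW domain oxidoreductase, stood at 9.34 ± 0.65 CPM (SD, n = 3) in WT young epidermis, 8.22 ± 0.60 (n = 3) in PKO young and 10.9 ± 3.06 (n = 3) in PKO cSCC. It was 0.857 ± 0.628 CPM (n = 3) in WKO young and 1.21 ± 0.72 (n = 3) in DKO cSCC. In DKO young it was 0.925 and 0.943 CPM in libraries 1 and 2 but 7.34 CPM in library 3, which goes against the label. Trp53 (ENSMUSG00000059552), the tumour suppressor p53, was 34.4 ± 4.95 CPM (n = 3) in WT young, 42.5 ± 5.21 (n = 3) in WKO young and 3.16 ± 1.99 (n = 3) in PKO cSCC. It remained at 21.8 and 19.2 CPM in PKO young 2 and 3, against 5.9 in PKO young 1. In DKO young it was 3.31, 3.26 and, in library 3, 21.1 CPM. In DKO cSCC it was 2.74 and 2.86 CPM in libraries 1 and 2 but 45.5 CPM in library 3, above every WT young library and against the label. These are therefore named the library labelled DKO young 3 and the library labelled DKO cSCC 3. With 3 libraries against 3, an exact two-sided permutation test cannot go below 0.1, the value it gave for Wwox in WKO against WT young and in DKO against PKO cSCC.

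**Figure D1:**
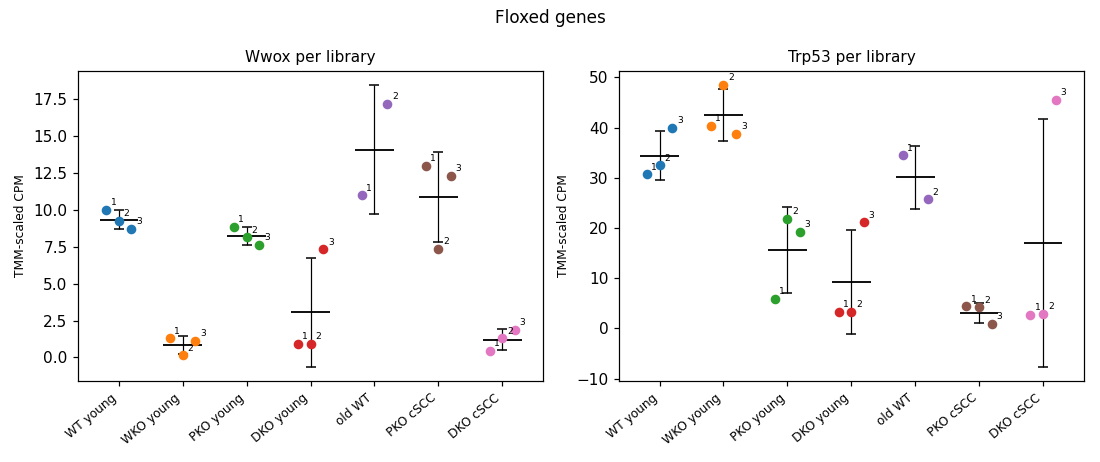
Wwox (left) and Trp53 (right) in TMM-scaled CPM for each of the 20 libraries, with replicate numbers, by group (points: libraries, horizontal lines: means, error bars: SD). Wwox was 7.34 CPM in the library labelled DKO young 3 and Trp53 was 45.5 CPM in the library labelled DKO cSCC 3, unlike the other libraries of those groups.

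Libraries also differed in markers of other cell types. T, NK and dendritic epidermal T cell markers summed to 1780 to 2210 CPM in the WT young libraries and 3630 CPM in PKO young 3, against 89.6 to 288 CPM in DKO young and 3.28 to 7.81 CPM in PKO cSCC. Erythrocyte genes, led by the alpha and beta globins, summed to 829 to 3500 CPM in WT young and 220 CPM in PKO young 3, and to at most 32.4 CPM in WKO young. Basal keratinocyte genes, which include Krt5 and Krt14, ran the other way, at 3490 to 4430 CPM in WT young, 4120 CPM in PKO young 3 and 15200 to 23700 CPM in WKO young. In the tumours, the library labelled DKO cSCC 3 had 16200 CPM of differentiated keratinocyte genes and 978 CPM of endothelial and mural genes, against at most 3640 and 281 CPM in the other 5. Xist, the RNA of the inactive X chromosome, was 466 CPM in DKO cSCC 1 and 1120 and 763 CPM in old WT, where the Y-linked Eif2s3y was at 0. Eif2s3y was 20 to 25.5 CPM in PKO cSCC, 26.8 CPM in DKO cSCC 2 with Xist at 13.9 CPM, 23.8 CPM in the library labelled DKO cSCC 3, and 25.1 CPM in WT young 1, so sex moves with several tumour comparisons.

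**Figure D2:**
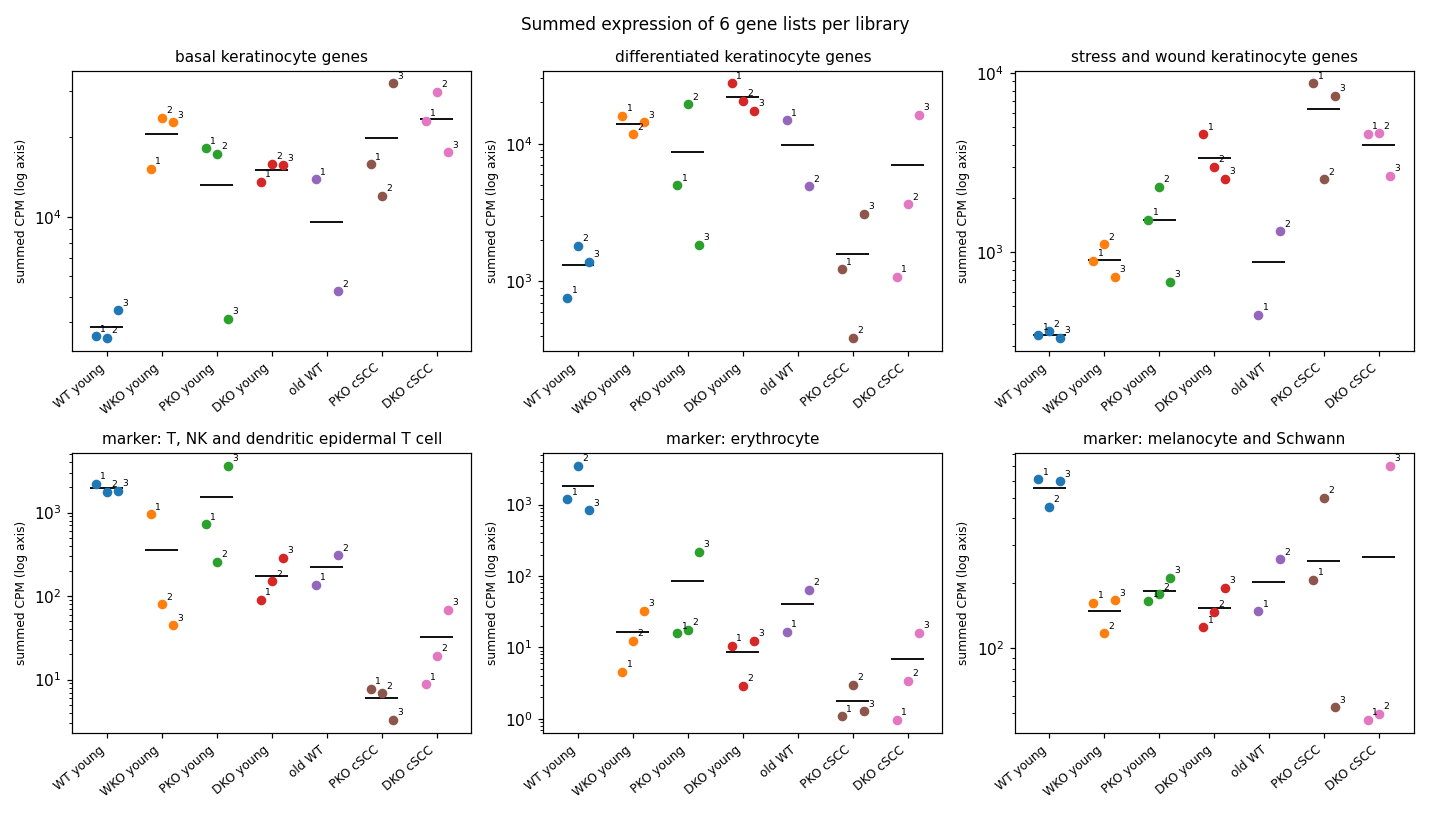
Summed CPM (log axis) of 6 gene lists in each of the 20 libraries, with replicate numbers, by group (points: libraries, lines: arithmetic means). WT young libraries and PKO young 3 lie low for basal keratinocyte genes (3490 to 4430 CPM) and high for T cell markers (1780 to 3630 CPM).

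The first comparison set carcinomas labelled as lacking both genes against carcinomas labelled as lacking p53 alone. This is the question of the series title, which names EMT. The DKO group holds the library labelled DKO cSCC 3, with Trp53 at 132% of the WT young mean. Hair follicle genes were higher in DKO cSCC, with 26 of 31 members positive and a median log2 fold change of 1.64 (camera adjusted p = 4.97e-10, and adjusted p = 0.311 with an estimated correlation). Their summed level ran the other way, at 3460 ± 888 CPM against 3980 ± 3710, with 8180 CPM in PKO cSCC 1. Krt25, a keratin of the inner root sheath, was 8.68 ± 3.2 CPM against 0.739 ± 0.339 (n = 3 each, log2 fold change 3.50, SE 0.53). Notch pathway genes were higher, with 11 of 14 positive and a median of 1.15 (adjusted p = 5.8e-05, and adjusted p = 0.166 with an estimated correlation). The receptor Notch3, which is also in the list of endothelial and mural markers, stood at 75.6 ± 46 CPM against 10.3 ± 2.54, and Notch1 at 260 ± 143 against 63.3 ± 21.7. Glycolysis and hypoxia genes were lower, with 29 of 32 negative and a median of -0.80 (adjusted p = 9.91e-11, and adjusted p = 0.467 with an estimated correlation), such as the glycolytic enzymes Eno1, at 310 ± 30.4 CPM against 744 ± 42.8, and Gpi1, at 116 ± 22.9 against 212 ± 6.57.

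Neither EMT list passed in this comparison. Mesenchymal genes of EMT had 27 of 34 members negative, a median of -0.45 and adjusted p = 0.532, and the EMT transcription factors a median of 0.06 and adjusted p = 0.186. Fibronectin (Fn1) was 109 ± 40.4 CPM in DKO cSCC against 2530 ± 4320 in PKO cSCC, and the collagen crosslinking enzyme Lox 1.39 ± 0.197 against 44.8 ± 77.1, with SDs in PKO above the means. PKO cSCC 2 alone held 7520 CPM of Fn1 and 134 CPM of Lox, against at most 57.3 and 0.511 CPM in PKO cSCC 1 and 3. Epithelial junction and identity genes were higher, with 27 of 40 positive and a median of 0.24 (adjusted p = 0.00806, and adjusted p = 0.467 with an estimated correlation). The tight junction gene Cldn4 was 9.06 ± 2.42 CPM against 1.26 ± 1.06. Differentiated keratinocyte genes, including the protease Klk7 at 66.3 ± 29.1 CPM against 5.61 ± 2.3, had 28 of 33 positive and a median of 1.16 (adjusted p = 3.03e-07, and adjusted p = 0.674 with an estimated correlation). Sebaceous gland genes had a median of 1.73 (adjusted p = 0.0164) and cell cycle genes one of -0.37 (adjusted p = 0.0082), with adjusted p = 0.679 and 0.714 with an estimated correlation. The protease inhibitor Cst6 had the smallest p of the genes the rule could name, at 211 ± 143 CPM against 4.41 ± 2.91 (log2 fold change 5.50, SE 0.69, adjusted p = 0.392), and the chemokine Cxcl12 stood at 45.9 ± 25.4 against 3.53 ± 1.12.

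Marker lists moved with these tumours too. Endothelial and mural genes had a median of 3.99 (adjusted p = 5.42e-09), T and NK cell genes 2.24 (adjusted p = 0.000191), skeletal muscle and adipocyte genes 2.99 (adjusted p = 0.0177), macrophage, monocyte and neutrophil genes 1.5 (adjusted p = 0.00579), Langerhans and dendritic cell genes 1.31 (adjusted p = 0.0186) and fibroblast genes 0.58 (adjusted p = 0.00027). Their adjusted p lay between 0.467 and 0.679 with an estimated correlation. Summed fibroblast genes were 1510 ± 419 CPM in DKO against 2020 ± 1890 in PKO cSCC, where PKO cSCC 2 had 4200 CPM. T and NK cell genes summed to only 32.1 ± 31.6 CPM in DKO against 5.98 ± 2.39 in PKO cSCC. Muscle and adipocyte genes summed to 34 ± 43 against 6.99 ± 7.56 CPM, so the medians of these lists rest on low levels. Dissociation and immediate early genes had a median of 0.68 (adjusted p = 4.99e-05) and NRF2 and glutathione genes one of -0.52 (adjusted p = 0.0331), with adjusted p = 0.5 and 0.679 with an estimated correlation. Skin lipid genes were called upward (adjusted p = 0.0217, and adjusted p = 0.679 with an estimated correlation) on a mean of 0.70 with a median of -0.01. Lists that did not pass had medians of -0.11 for interferon-stimulated genes, -0.11 for DNA damage response, 0.03 for p53 targets, 0.06 for TGF-beta, 0.05 for Wnt, -0.02 for YAP/TAZ, -0.01 for stress and wound genes, 0.02 for cytokines, -0.04 for carcinoma-associated genes, 0.69 for melanocyte and Schwann and 1.55 for erythrocyte markers, and -0.0045 for basal keratinocyte genes, whose mean was 0.0099. Means and medians also differed in sign for TGF-beta (mean -0.12), stress and wound genes (0.17) and cytokines (-0.20), and YAP/TAZ targets, with a mean of -0.12, had an upward test. Adjusted over the list alone, 7 hair follicle, 4 Notch, 12 endothelial, 3 muscle and adipocyte and 1 differentiated keratinocyte gene were higher and 3 glycolysis genes lower, against 0 list genes adjusted over all genes tested.

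By gene, edgeR called 1 of 16526 at the threshold, the ribosomal pseudogene Rpl34-ps1, which falls outside the naming rule and was chosen after its value was seen. An unadjusted p under 0.05 was found for 1338 genes, and DESeq2 called 235 and voom 0. Leaving out PKO cSCC 1, 2 or 3 or DKO cSCC 2 left no call. Wwox itself had a log2 fold change of -3.23 (SE 0.56, adjusted p = 0.608) and Trp53 one of 2.35 (SE 1.14, adjusted p = 0.62), which turned to -0.20 without the library labelled DKO cSCC 3. With each library left out in turn, calls ended for cell cycle, skin lipid and Langerhans genes without PKO cSCC 1 (adjusted p = 0.532, with the direction of cell cycle genes turned, 0.341 and 0.11). Junction, NRF2 and skin lipid genes lost theirs without PKO cSCC 2 (0.0556, 0.0531 and 0.403), as did sebaceous, cell cycle, NRF2, fibroblast, macrophage, Langerhans and muscle genes without PKO cSCC 3 (0.149, 0.0623, 0.295, 0.11, 0.167, 0.0649 and 0.119). They also ended for NRF2 genes without DKO cSCC 1 (0.0503) and for sebaceous, cell cycle, NRF2, skin lipid, macrophage, Langerhans and muscle genes without the library labelled DKO cSCC 3 (0.535, 0.399, 0.0975, 0.16, 0.155, 0.535 and 0.155).

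PKO carcinomas were next set against old WT epidermis, with sex differing between the groups. Cell cycle genes were higher, with all 40 measured members positive and a median log2 fold change of 2.53 (camera adjusted p = 4.67e-16, and adjusted p = 0.628 with an estimated correlation). The ubiquitin-conjugating enzyme Ube2c stood at 29.1 ± 15.2 CPM (n = 3) against 1.42 ± 0.19 (n = 2). Stress and wound keratinocyte genes had 26 of 30 positive and a median of 5.20, or 3.82 with 5 genes at 0 in one group set to their bound of 3 counts over the group (adjusted p = 0.00199, and adjusted p = 0.666 with an estimated correlation). The wound keratins Krt6a and Krt16 stood at 1600 ± 1210 and 495 ± 569 CPM against 11.4 ± 2.38 and 5.02 ± 0.442. Glycolysis and hypoxia genes had 29 of 32 positive and a median of 1.86 (adjusted p = 2.11e-11, and adjusted p = 0.628 with an estimated correlation), as for hexokinase 2 (Hk2), at 94.2 ± 28.5 CPM against 16.8 ± 4.1.

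Mesenchymal genes of EMT were higher, with 31 of 34 positive and a median of 1.41, and epithelial junction genes lower, with 34 of 40 negative and a median of -0.69 (adjusted p = 0.00912 and 0.000366, and adjusted p = 0.666 and 0.628 with an estimated correlation). Cd44, the hyaluronan receptor, was 547 ± 262 CPM against 105 ± 12.1, and Cldn4 1.26 ± 1.06 against 18.2 ± 4.12. Snai2, an EMT transcription factor, was 61.7 ± 10.6 CPM against 17.2 ± 9.36, in a list that did not pass (median 0.72). Fibroblast markers summed to 809 to 4200 CPM against 273 to 1020 CPM, in a list with a median of 0.30, a mean of -0.08 and a downward test that did not pass (adjusted p = 0.591). Basal keratinocyte genes were higher (median 1.04, adjusted p = 0.00213), as were interferon-stimulated genes (0.86, adjusted p = 0.00199), cytokines (2.19, adjusted p = 0.0365) and DNA damage response genes (0.53, adjusted p = 0.0275). Sebaceous genes (-1.78, adjusted p = 0.00487), hair follicle genes (-1.07, adjusted p = 0.0111), differentiated keratinocyte genes (-0.81, adjusted p = 0.012) and immediate early genes (-0.58, adjusted p = 0.0365) were lower. Adjusted p for these lists lay between 0.628 and 0.764 with an estimated correlation. Summed levels did not follow the medians for hair follicle genes, at 3980 ± 3710 CPM against 1220 ± 106, or for cytokines, at 443 ± 63.7 against 444 ± 170. T and NK cell markers were also lower (-4.67, adjusted p = 3.31e-08), with erythrocyte markers (-4.38, adjusted p = 0.00549), each with adjusted p = 0.628 with an estimated correlation. Adjusted over the list alone, 37 cell cycle, 21 glycolysis and 15 stress genes were higher and 13 T cell genes lower, against 0 adjusted over all genes tested.

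Trp53 had a log2 fold change of -3.18 (SE 1.23, adjusted p = 0.149) and Wwox one of -0.29 (SE 0.56, adjusted p = 0.758), which turned to 0.061 without old WT 2. By gene, edgeR called 2 of 16526, Rps2 upward and Rpl34-ps1 downward, both outside the naming rule and chosen after their values were seen, and 4581 had an unadjusted p under 0.05. Adjusted p for the 5 genes of the rule, Robo2, Klk10, Pcdhgc3, Xaf1 and Krt25, came to 0.05, just above the threshold, as part of 163 genes from 0.05 to 0.055, with log2 fold changes of 3.04, 3.41, 2.26, 3.54 and -4.57. The count was 3876 with all 20 libraries in the fit, 2587 by DESeq2, 326 with a 10 CPM minimum, 59 with TMMwsp and 1 by voom, and it ran from 0 without PKO cSCC 1 or 3 to 67 without PKO cSCC 2, with 14 and 30 without old WT 1 and 2. List calls ended for mesenchymal, differentiated, interferon and immediate early genes without old WT 1 (adjusted p = 0.155, 0.333, 0.131 and 0.55), DNA damage genes without old WT 2 (0.19), DNA damage and immediate early genes without PKO cSCC 1 (0.142 and 0.112), and mesenchymal, differentiated, hair follicle and cytokine genes without PKO cSCC 2 (0.131, 0.178, 0.141 and 0.0623).

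DKO carcinomas were set against the same old WT libraries. Cell cycle genes again had 40 of 40 members positive, with a median log2 fold change of 2.25 (camera adjusted p = 2.07e-20), stress and wound genes 28 of 30 with a median of 5.29, or 4.06 with 5 genes at their bound (adjusted p = 7.3e-06), and glycolysis genes 28 of 32 with a median of 0.96 (adjusted p = 2.94e-07). Adjusted over the list alone, 32, 12 and 7 of them were higher, against 0 adjusted over all genes tested. Each of these had adjusted p = 0.539 with an estimated correlation. Krt6a was 1300 ± 472 CPM (n = 3) against 11.4 ± 2.38 (n = 2), Ube2c 16.1 ± 3.41 against 1.42 ± 0.19 and Hk2 74.4 ± 10.8 against 16.8 ± 4.1. The matrix metalloproteinase gene Mmp10, at 0 in both old WT libraries, was at least 39.1-fold higher against a floor of 3 counts over the group. Mesenchymal genes of EMT had 25 of 34 positive and a median of 0.98, and epithelial junction genes 29 of 40 negative and a median of -0.50 (adjusted p = 0.00181 and 0.00239, and adjusted p = 0.667 and 0.539 with an estimated correlation), although summed junction genes were 9150 ± 1850 CPM against 8460 ± 4010. Fibroblast markers summed to 1250 to 1990 CPM in the DKO carcinomas against 273 to 1020 CPM in old WT, in a list that did not pass (median 0.26, adjusted p = 0.0676).

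Basal keratinocyte genes (median 0.88, adjusted p = 9.44e-05), interferon-stimulated genes (0.96, adjusted p = 9.44e-05), cytokines (1.58, adjusted p = 0.00181), Wnt pathway genes (0.35, adjusted p = 0.0386) and DNA damage response genes (0.45, adjusted p = 0.0483) were higher. T and NK cell markers (-2.47, adjusted p = 4.3e-09) and erythrocyte markers (-2.36, adjusted p = 0.0034) were lower and endothelial markers higher (1.72, adjusted p = 0.0277). These lists had adjusted p of 0.539 to 0.774 with an estimated correlation. Wwox had a log2 fold change of -3.52 (SE 0.59, adjusted p = 0.164) and Trp53 one of -0.83 (SE 1.19, adjusted p = 0.766), or -3.39 without the library labelled DKO cSCC 3 (adjusted p = 0.111). No gene was called by edgeR, with 2402 at an unadjusted p under 0.05, 743 by DESeq2, 1 by voom, and 788 by edgeR with all 20 libraries in the fit. Leaving out old WT 1 gave 2 calls and leaving out DKO cSCC 1 gave 1. List calls ended for mesenchymal, junction, interferon and endothelial genes without old WT 1 (adjusted p = 0.259, 0.194, 0.118 and 0.633) and for Wnt, DNA damage and erythrocyte genes without old WT 2 (0.49, 0.425 and 0.139). They also ended for Wnt and DNA damage genes without DKO cSCC 1 (0.0608 and 0.134), DNA damage genes without DKO cSCC 2 (0.215) and endothelial genes without the library labelled DKO cSCC 3 (0.607).

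**Figure D3:**
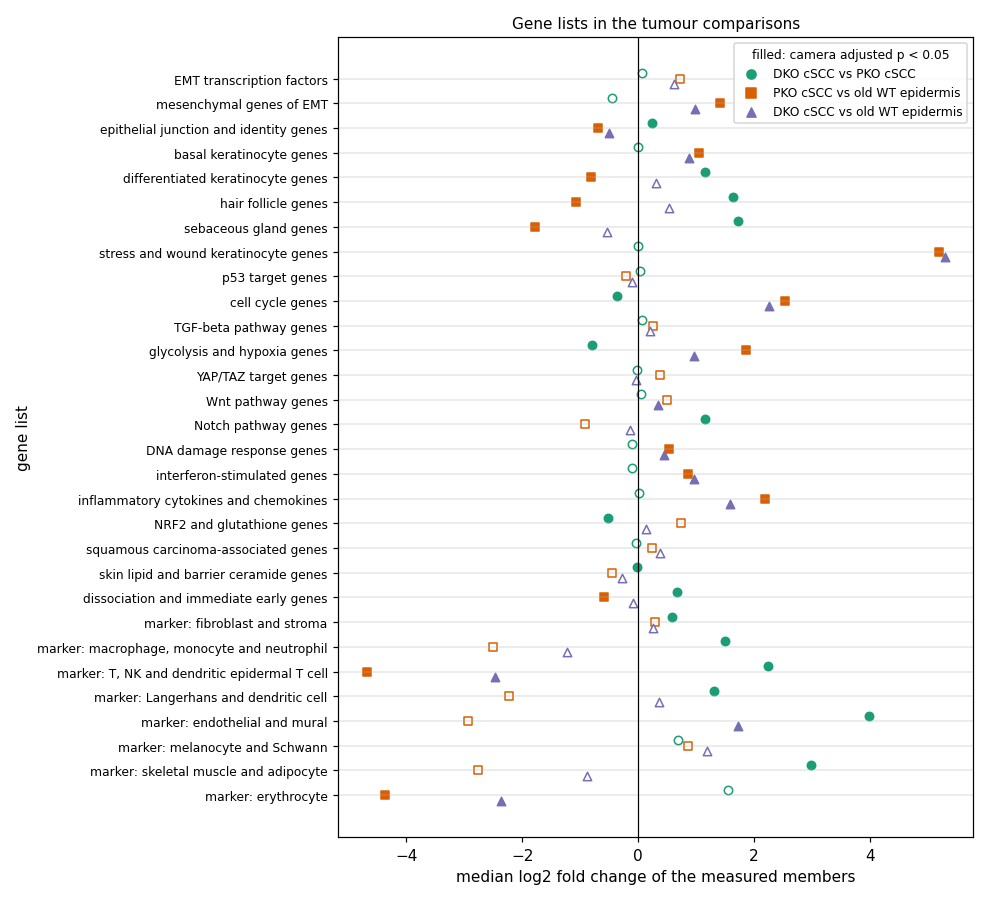
Median log2 fold change of the measured members (horizontal axis) of 30 gene lists (vertical axis) in 3 tumour comparisons, filled where camera with a preset correlation gave an adjusted p under 0.05. Stress and wound keratinocyte genes lie at 5.20 and 5.29 against old WT and glycolysis and hypoxia genes at -0.80 in DKO against PKO cSCC. With an estimated correlation none of the lists passed.

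In young epidermis, deletion of Wwox alone was compared with WT. Junction and identity genes rose, with 27 of 40 called higher, or 35 adjusted over the list alone, and a median log2 fold change of 2 (camera adjusted p = 2.21e-12, and adjusted p = 0.49 with an estimated correlation), such as the desmosomal plakophilin Pkp1 (2.75, adjusted p = 0.0126). Among basal keratinocyte genes 14 of 21 rose, or 16 adjusted over the list alone (median 2.10, adjusted p = 8.13e-07), and Krt14 was 3720 ± 1350 CPM against 464 ± 70.7 (n = 3 each, log2 fold change 3, adjusted p = 0.0126). Among differentiated keratinocyte genes 15 of 34 rose, or 20 adjusted over the list alone (median 2.12, adjusted p = 8.13e-07), with Krt1 at 3.52 (adjusted p = 0.0138). Sebaceous genes rose in 8 of 16 (median 1.85, adjusted p = 7.61e-05) and skin lipid genes in 10 of 17, with 1 lower (median 2.30, adjusted p = 0.000125). Each of these lists had adjusted p = 0.49 with an estimated correlation.

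Markers of other cell types moved with the same groups. All 6 erythrocyte genes fell (median -7.12, or -6.86 with 1 gene at its bound, adjusted p = 8.32e-05), with Hba-a1 at 4.72 ± 3.73 CPM against 578 ± 471. So did 7 of 12 melanocyte and Schwann genes (median -2.44, adjusted p = 4.35e-05), 6 of 18 macrophage and neutrophil genes (-2.77, adjusted p = 0.000185), 4 of 11 muscle and adipocyte genes (-2.67, adjusted p = 0.00117) and 3 of 17 T cell genes (-2.90, adjusted p = 1.9e-06). Endothelial (-1.66, adjusted p = 0.00436) and fibroblast markers (-1.2, adjusted p = 0.0207) were lower as lists, although summed endothelial markers were 194 ± 55.5 CPM against 177 ± 28.6. The estimated correlation gave adjusted p = 0.703 for fibroblast markers and 0.49 for the others. Among the lists of cell states, 10 of 27 interferon-stimulated genes fell (median -2.15, adjusted p = 0.0297). Of mesenchymal genes of EMT 3 of 32 fell, namely Plaur, Msn and Itgb3 (median -0.64, adjusted p = 0.0297), close to the share over all genes tested, 1386 of 16627. These lists had adjusted p = 0.703 and 0.589 with an estimated correlation. The EMT transcription factors (-2.10, adjusted p = 0.0442) held 1 member that rose, Snai2 (1.2), and 1 that fell, Tcf4 (-0.90). Immediate early genes (1.06, adjusted p = 5.05e-05), p53 targets (0.46, adjusted p = 0.0291) and carcinoma-associated genes (0.80, adjusted p = 0.0349) were higher. For these last 4 lists adjusted p = 0.49 with an estimated correlation. List calls ended for mesenchymal and interferon genes without WT young 1 (adjusted p = 0.0835 and 0.387), EMT transcription factors, mesenchymal, p53 target, carcinoma-associated and fibroblast genes without WT young 3 (0.0862, 0.0532, 0.0618, 0.0622 and 0.0965), and interferon and carcinoma-associated genes without WKO young 1 (0.0752 and 0.0654). They also ended for EMT transcription factors, carcinoma-associated and fibroblast genes without WKO young 2 (0.0529, 0.0529 and 0.0936), and for mesenchymal and carcinoma-associated genes without WKO young 3 (0.0977 and 0.0708). Without the library labelled DKO young 3, calls ended for carcinoma-associated genes if PKO young 2 was left out too (0.0654) and for interferon genes if PKO young 3 was (0.0546).

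The largest rises were of the milk protein genes Csn1s2a (11.67, SE 3.47), Csn2 (11.10, SE 3.02) and Csn1s1 (8.79, SE 2.62), followed by the cytochrome Cyp2g1 (7.59), Serpinb3b (5.58), H2-Eb1 (5.52), Pyy (5.44), Bex1 (5.17), Mettl7b (5.11) and Serpina3i (5.09). Csn2 was 547 CPM in WKO young 2 against 13.7 and 12.3 CPM in WKO young 1 and 3. Cartpt, Trem1, Myh1 and Fpr2 had no counts in WKO and were at least 627, 145, 84.6 and 76-fold lower, followed by Ifit1bl1 (-9.76), Rsad2 (-8.47), Tnn (-8.35), Slc12a1 (-8.25), Csf3r (-8.17) and Ms4a4c (-8.14), with adjusted p from 0.0126 to 0.0423 over the 20 genes. Wwox fell by 3.44 on the log2 scale (SE 0.87, adjusted p = 0.0233), a call that ended without WT young 1 or 2 or WKO young 2 or 3 (adjusted p = 0.06, 0.0573, 0.0711 and 0.0676). Trp53 had a log2 fold change of 0.30 (SE 0.66, adjusted p = 0.769). In all 2177 genes rose and 1386 fell by edgeR, of 16627. The count of 3563 was 1088, 1228, 893 and 965 without WT young 1 or 2 or WKO young 2 or 3, 7304 by voom and 2199 with all 20 libraries in the fit.

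PKO young epidermis was compared with the same WT libraries, and its 3 libraries differed in composition and in Trp53. Trp53 stood at 63.2% and 55.8% of the WT young mean in PKO young 2 and 3, against 17.1% in PKO young 1, and had a log2 fold change of -1.14 (SE 0.67, adjusted p = 0.307). Wwox had one of -0.19 (SE 0.77, adjusted p = 0.897). Junction genes were positive in 40 of 40 (median 1.60, camera adjusted p = 5.03e-15, and adjusted p = 0.517 with an estimated correlation), with 35 higher adjusted over the list alone and 0 over all genes tested. Immediate early genes, which respond to stress and dissociation, were positive in 24 of 27 (median 1.45, adjusted p = 4.2e-12), with Egr1 at 2.31 and Jun at 1.79, and 18 were higher adjusted over the list alone. Erythrocyte markers (-4.75, adjusted p = 4.19e-06) and melanocyte markers (-1.54, adjusted p = 5.42e-06) were lower. The last 3 lists each had adjusted p = 0.363 with an estimated correlation.

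Basal (median 1.39, adjusted p = 5.14e-06) and differentiated keratinocyte genes (2.14, adjusted p = 6.86e-05), skin lipid (1.64, adjusted p = 0.00614), sebaceous (0.89, adjusted p = 0.0456), YAP/TAZ target (0.57, adjusted p = 0.0268) and glycolysis genes (0.26, adjusted p = 0.00127) were higher. Macrophage (-2.50, adjusted p = 3.14e-05), muscle (-2.80, adjusted p = 0.000569), endothelial (-1.05, adjusted p = 0.0138) and T cell markers (-0.71, adjusted p = 0.000996) were lower. These lists each had adjusted p = 0.581 with an estimated correlation. The p53 target list did not pass (median 0.20). Summed p53 targets were 1240 ± 30 CPM in WT young, 2750 ± 178 in WKO, 2230 ± 999 in PKO and 3580 ± 503 in DKO young. In DKO young, libraries 1 and 2 had Trp53 at 9.6% and 9.48% of the WT young mean, so these sums did not fall with Trp53. Basal keratinocyte genes summed to 3490 to 4430 CPM in WT young and 13600 to 15900 CPM in DKO young. With this difference between the libraries, the sums cannot show whether p53 targets changed within keratinocytes. Only Rpl26, a ribosomal protein gene outside the naming rule and chosen after its value was seen, was called (log2 fold change 4.21, adjusted p = 0.000203), with 4174 genes at an unadjusted p under 0.05. A further 491 genes had an adjusted p from 0.05 to 0.055, and 1921 had one under 0.1, so the count rests on where the threshold lies. Adjusted p was 0.0539 for the 5 genes of the rule, Vmn1r76, Gpld1, Pim3, Olfr639 and Ifi27. Without PKO young 3 the count was 2998, and it was 3 without PKO young 2, 2 without WT young 3, 2168 by DESeq2 and 1883 by voom. List calls ended for YAP/TAZ targets without WT young 2 (adjusted p = 0.0739), sebaceous genes without WT young 3 (0.106), and sebaceous, YAP/TAZ and endothelial genes without PKO young 1 (0.348, 0.133 and 0.0707).

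DKO young epidermis differed from WT in 4629 of 16627 genes by edgeR, 2623 up and 2006 down. The group holds the library labelled DKO young 3, with Wwox at 78.6% and Trp53 at 61.4% of the WT young mean. Differentiated keratinocyte genes rose in 26 of 34, or 28 adjusted over the list alone (median log2 fold change 3.51, camera adjusted p = 1.83e-12), as with the protease inhibitor Spink5 (4.92, adjusted p = 0.00614). Junction genes rose in 30 of 40, or 32 adjusted over the list alone (median 2.15, adjusted p = 2.51e-13), as with E-cadherin, Cdh1, at 771 ± 37.9 CPM against 273 ± 23.2 (n = 3 each). Stress and wound genes rose in 11 of 22, with 2 lower (median 3.33, adjusted p = 0.00108), immediate early genes in 20 of 27 (2.38, adjusted p = 4.13e-11), basal keratinocyte genes in 15 of 21, with 2 lower (1.84, adjusted p = 8.71e-05), and skin lipid genes in 13 of 17 (2.73, adjusted p = 1.02e-05). These lists each had adjusted p = 0.533 with an estimated correlation.

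The AP-1 subunit Fosl1 rose most among named genes, at 345 ± 69 CPM against 2.21 ± 1.49 (log2 fold change 7.27, SE 1.19, adjusted p = 0.00614), followed by Serpinb3b (7.04), the epithelial transcription factor Elf3 (6.67), Cldn4 (6.33), Pyy (6.26), the EGF receptor ligands Epgn (6.21) and Ereg (6), Slc6a14 (6.04), the skin chemokine Ccl27a (5.94) and Krt16 (5.89). The high-affinity IgG receptor Fcgr1 had no counts in DKO and was at least 439-fold lower, with Ifit1bl1, Trem1, Treml4, Cxcr3, Myh1, Cd177, Rspo2 and Pira2 at least 358, 134, 101, 87.7, 78.1, 76.1, 74 and 69.1-fold lower, and Ms4a4c at -9.70. T cell genes fell in 11 of 17, or 17 adjusted over the list alone (median -3.88, adjusted p = 7.73e-06), erythrocyte genes in 5 of 6 (-7.58, adjusted p = 0.000681), melanocyte genes in 8 of 12 (-2.47, adjusted p = 0.000111), macrophage genes in 6 of 18 (-3.31, adjusted p = 0.00026) and muscle genes in 6 of 11 (-3.33, adjusted p = 0.00232). Endothelial (-2.30, adjusted p = 0.00646) and fibroblast markers (-0.76, adjusted p = 0.0027) were lower as lists, although summed endothelial markers were 216 ± 5.29 CPM against 177 ± 28.6. For these lists adjusted p lay between 0.533 and 0.591 with an estimated correlation.

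Cell cycle genes fell in 7 of 40, or 2 adjusted over the list alone (median -0.87, adjusted p = 0.000681), among them Mki67 and Mcm3, and mesenchymal genes of EMT in 5 of 32, with 1 higher (-0.78, adjusted p = 0.032), among them N-cadherin, Cdh2 (-4.56, adjusted p = 0.0186). The estimated correlation gave these adjusted p = 0.591 and 0.585. Glycolysis genes (0.34, adjusted p = 0.00167), cytokines (2.02, adjusted p = 0.024) and carcinoma-associated genes (0.70, adjusted p = 0.0295) were higher, each with adjusted p = 0.533 with an estimated correlation. Wwox had a log2 fold change of -1.64 (SE 0.80, adjusted p = 0.147) and Trp53 one of -1.93 (SE 0.69, adjusted p = 0.0591), or -3.31 and -3.39 without the library labelled DKO young 3 (adjusted p = 0.0125 and 0.00856). The count of 4629 was 4045 without that library, 1609 and 2959 without DKO young 1 or 2, and 2958 and 2726 without WT young 1 or 2. List calls ended for mesenchymal genes without WT young 1 or DKO young 1 or 2 (adjusted p = 0.103, 0.1 and 0.0747), carcinoma-associated genes without DKO young 2 (0.0889), and cytokines without WT young 3 or the library labelled DKO young 3 (0.341 and 0.0912), or without the latter and PKO young 3 (0.131).

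**Figure D4:**
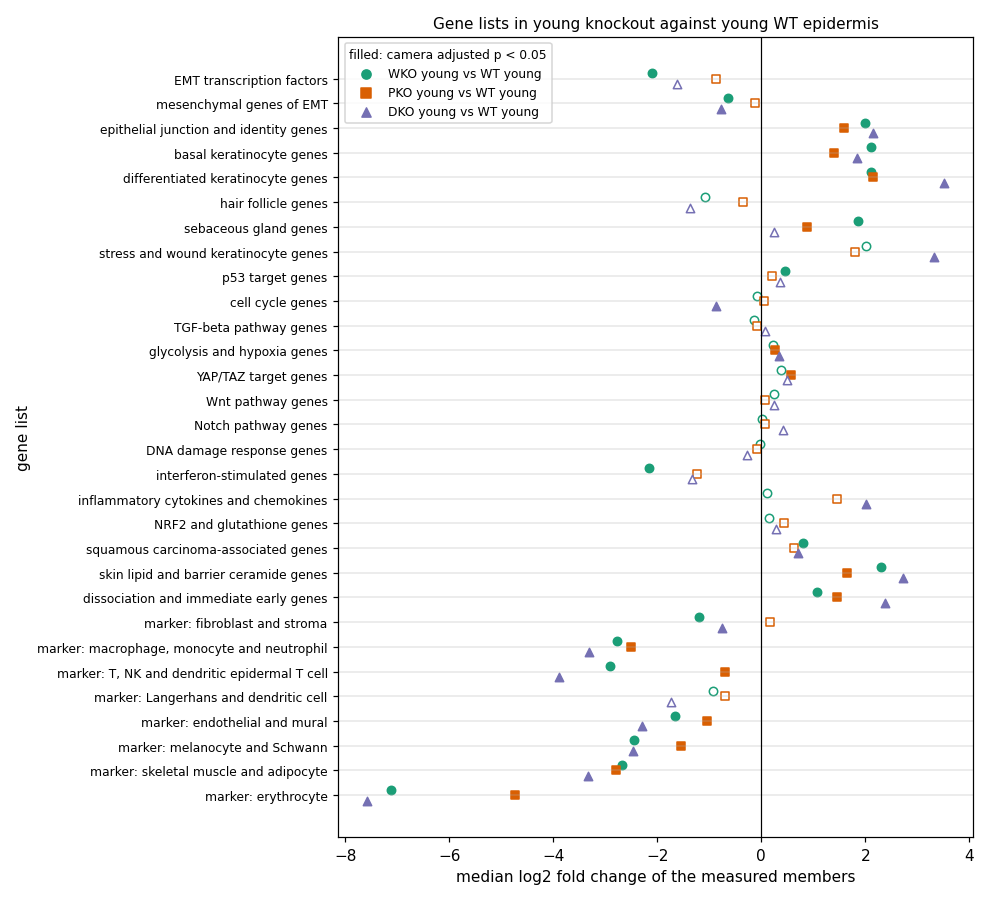
Median log2 fold change of the measured members (horizontal axis) of 30 gene lists (vertical axis) in young WKO, PKO and DKO epidermis against young WT, filled where camera with a preset correlation gave an adjusted p under 0.05. Differentiated keratinocyte genes lie at 3.51 in DKO and erythrocyte markers at -7.12, -4.75 and -7.58. With an estimated correlation none of the lists passed.

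DKO was set against PKO young epidermis, which differ by the label for Wwox. Wwox was 3.07 ± 3.7 CPM against 8.22 ± 0.604 (n = 3 each), since the library labelled DKO young 3 had 7.34 CPM. Its log2 fold change was -1.46 (SE 0.80, adjusted p = 0.358), or -3.13 without that library (adjusted p = 0.117), and that of Trp53 was -0.78 (SE 0.67, adjusted p = 0.548), or -2.25 without it (adjusted p = 0.117). Differentiated keratinocyte genes were higher, with 33 of 34 positive and a median log2 fold change of 1.36 (camera adjusted p = 6.05e-15), and cell cycle genes lower, with 39 of 40 negative and a median of -0.78 (adjusted p = 1.05e-09). Skin lipid (1.06, adjusted p = 7.69e-07), stress and wound (1.12, adjusted p = 6.88e-05), immediate early (0.70, adjusted p = 0.000198), junction (0.45, adjusted p = 0.00033) and cytokine genes (0.58, adjusted p = 0.0337) were higher. Mesenchymal genes of EMT were lower, with 24 of 32 negative and a median of -0.78 (adjusted p = 0.000613), with Vim, the intermediate filament vimentin, at 175 ± 177 CPM against 897 ± 947 (n = 3 each). T cell markers (-3.23, adjusted p = 3.41e-05), fibroblast markers (-0.74, adjusted p = 3.7e-05) and melanocyte markers (-0.63, adjusted p = 0.0348) were lower with them. PKO young 3 had 3630 CPM of T cell markers and 4120 CPM of basal keratinocyte genes. DKO young had 89.6 to 288 and 13600 to 15900 CPM of these. Summed mesenchymal genes overlapped, at 1400 to 2420 CPM in DKO against 2090 to 4670 CPM in PKO young. An effect of Wwox and a difference in cell composition were not told apart here. All 11 lists had adjusted p = 0.735 with an estimated correlation. Adjusted over the list alone, 14 T cell genes were lower and 3 cytokine genes higher and 1 lower, against 0 adjusted over all genes tested.

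No gene was called by edgeR, with 2742 at an unadjusted p under 0.05, 177 by DESeq2 and 0 by voom. The 5 genes of the rule, Mindy2, Hist1h1c, Bace1, Arhgef3 and Uba6, each had adjusted p = 0.274. Without PKO young 2, the library closest to the library labelled DKO young 3, edgeR called 403 genes, and without both it called 693. List calls ended for cytokines without PKO young 1 (adjusted p = 0.119), melanocyte genes without PKO young 2 (0.06), junction, cytokine and melanocyte genes without PKO young 3 (0.132, 0.112 and 0.0645), melanocyte genes without DKO young 1 (0.183) and cytokines without the library labelled DKO young 3 (0.216). Without that library, cytokines also failed if PKO young 2 or 3 was left out too (0.0726 and 0.342), and junction genes if PKO young 3 was (0.146).

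Old WT epidermis was compared with young WT for change with age without gene deletion, but sex differs in part between these groups, and markers of cell types differ too. Old WT 1 and 2 had Xist at 1120 and 763 CPM and Eif2s3y at 0. WT young 1 had Xist at 0.218 and Eif2s3y at 25.1 CPM, and WT young 2 had Eif2s3y at 1.84 CPM. Summed T cell markers were 137 to 306 CPM in old against 1780 to 2210 CPM in young WT, and erythrocyte genes 16.5 to 64 against 829 to 3500 CPM. Basal keratinocyte genes were 5240 to 13900 against 3490 to 4430 CPM. Langerhans and dendritic cell markers ran from 159 to 4540 CPM between the old libraries. A change with age and a difference in cell composition cannot be told apart here. Epithelial junction genes were higher, with 3 of 40 called, Tjp3, Marveld3 and Spint2, or 30 adjusted over the list alone, and 39 positive (median log2 fold change 1.61, camera adjusted p = 1.63e-13, and adjusted p = 0.569 with an estimated correlation). Cell cycle genes were lower in 40 of 40, with Pcna called (median -0.85, adjusted p = 8.35e-07, and adjusted p = 0.649 with an estimated correlation). Basal (1.38, adjusted p = 0.000296) and differentiated keratinocyte (1.61, adjusted p = 2.97e-05), sebaceous (0.82, adjusted p = 0.02) and skin lipid genes (1.80, adjusted p = 0.000286) were higher. Hair follicle (-1.36, adjusted p = 0.00517), interferon-stimulated (-2.32, adjusted p = 0.00296) and mesenchymal genes (-0.69, adjusted p = 0.0398) were lower, with Cd44 called at 105 ± 12.1 CPM (n = 2) against 358 ± 98 (n = 3). T cell (-3.29, adjusted p = 2.81e-08), erythrocyte (-5.40, adjusted p = 3.63e-06), melanocyte (-2.07, adjusted p = 2.8e-05), muscle (-2.50, adjusted p = 0.00414), fibroblast (-1.79, adjusted p = 0.00483) and macrophage markers (-0.52, adjusted p = 0.0139) were lower with them. These lists had adjusted p of 0.534 to 0.654 with an estimated correlation.

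Among genes, the acute phase protein gene Saa1 rose most, at 44.1 ± 62.2 CPM (n = 2) against 0.0188 ± 0.0326 (n = 3, log2 fold change 10.62, SE 2.35, adjusted p = 0.0459), followed by Cel (9.02), Folr1 (8.88), Col9a1 (8.32), Cyp2g1 (7.43), Cck (7.13), Muc1 (6.04), Myo5c (5.86), Slc28a3 (5.62) and Cdhr1 (5.36). Saa1 and Col9a1 stood at 88.1 and 202 CPM in old WT 2, against 0.164 and 2.95 CPM in old WT 1. Old WT 2 also had the highest levels of the casein milk protein genes, given below. Foxp3, the transcription factor of regulatory T cells, fell most (-8.17, SE 1.76, adjusted p = 0.0439), followed by Blk (-6.87), Ccr6 (-6.38), Fstl4 (-5.22), Slc6a17 (-5.20), the melanocyte lineage factor Pax3 (-5.12), Prkg2 (-4.59), the melanin enzyme gene Dct (-4.40), Slc27a6 (-2.96) and Stx11 (-2.64). Wwox had a value of 0.60 (SE 0.82, adjusted p = 0.703) and Trp53 one of -0.18 (SE 0.72, adjusted p = 0.908), which turned to 0.020 without old WT 2. In all 305 genes rose and 46 fell by edgeR, of 17622. The count of 351 was 0 without WT young 1, 2 or 3, 57 without old WT 2, 2049 by DESeq2, and 129 with 34 up and 95 down when only these libraries were fitted. Without WT young 1, calls ended for mesenchymal, interferon and macrophage genes (adjusted p = 0.147, 0.155 and 0.12), and for sebaceous genes without WT young 3 (0.0538) or old WT 2 (0.0982). Without old WT 1 they ended for basal, sebaceous, interferon, skin lipid, fibroblast and muscle genes (0.131, 0.0638, 0.0946, 0.0877, 0.362 and 0.132) and for mesenchymal and macrophage genes, whose direction turned (0.537 and 0.169).

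Whether the effect of Wwox deletion depended on p53, as labelled, was tested as a difference of effects in young epidermis. The background labelled p53-deleted holds PKO young 2 and 3 and the library labelled DKO young 3. Their Trp53 was 63.2%, 55.8% and 61.4% of the WT young mean, and PKO young 3 had basal and T cell marker sums of 4120 and 3630 CPM. The p53-intact side rests on WT young libraries that also differed from WKO in markers of cell types. Erythrocyte genes summed to 829 to 3500 CPM in WT young against 4.56 to 32.4 CPM in WKO. Basal genes summed to 3490 to 4430 CPM against 15200 to 23700 CPM. The values below are therefore not a clean test of dependence on p53. Junction genes (median -1.39, camera adjusted p = 1.79e-07), basal keratinocyte genes (-1.87, adjusted p = 2.27e-06), sebaceous genes (-1.92, adjusted p = 3.14e-06) and cell cycle genes (-0.65, adjusted p = 8.35e-05) had a lower effect in the p53-deleted background, and erythrocyte markers a higher one (3.86, adjusted p = 0.00838). Adjusted p was 0.885 to 0.894 with an estimated correlation. The call of erythrocyte markers ended without the libraries labelled DKO young 3 and PKO young 2 (adjusted p = 0.0735). Adjusted over the list alone, 12 basal, 8 sebaceous and 1 cell cycle gene had lower and 3 erythrocyte genes higher effects, against 0 adjusted over all genes tested. Krt14 had the value -3.02 (adjusted p = 0.111), Wwox 1.99 (adjusted p = 0.346) and Trp53 -1.08 (adjusted p = 0.55). Without the library labelled DKO young 3 Wwox had 0.31 (adjusted p = 0.856) and Trp53 -2.55 (adjusted p = 0.0958). No gene was called by edgeR, with 3382 at an unadjusted p under 0.05, 1103 by DESeq2, 708 by voom, 1199 by edgeR without PKO young 3, 1 without WT young 3 and 2 without the library labelled DKO young 3. The number of called lists went from 5 to 8, 10 and 9 without WT young 1, 2 and 3, 11 and 8 without WKO young 1 and 3, 15 without PKO young 3, and 8 and 9 without DKO young 1 and 2. The 5 genes with the smallest p were Vmn1r76, Mettl7b, Dbp, Gpld1 and Ddt, each with adjusted p = 0.111.

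The same difference of effects was taken between tumours and young epidermis labelled p53-deleted. In that epidermis PKO young 2 and 3 and the library labelled DKO young 3 had Trp53 at 63.2%, 55.8% and 61.4% of the WT young mean. Among the tumours the library labelled DKO cSCC 3 had 132%. Glycolysis and hypoxia genes (median -0.94, camera adjusted p = 2.6e-10) and stress and wound genes (-1.29, adjusted p = 0.00296) had a lower Wwox effect in tumours. Hair follicle (2.73, adjusted p = 1.56e-06), Notch (1.44, adjusted p = 0.0105), Wnt (0.59, adjusted p = 0.0105), sebaceous (1.86, adjusted p = 0.0137) and cell cycle genes (0.41, adjusted p = 0.00197) had a higher one. So had the endothelial (5.56, adjusted p = 1.02e-06), T cell (5.37, adjusted p = 0.000126), muscle (3.59, adjusted p = 0.0137), macrophage (2.14, adjusted p = 0.0105) and fibroblast markers (1.40, adjusted p = 1.76e-06). Adjusted p was 0.245 to 0.786 with an estimated correlation. Adjusted over the list alone, 16 T cell, 10 endothelial, 9 hair follicle, 6 sebaceous, 3 Notch and 2 Wnt genes had higher and 7 glycolysis genes lower effects, against 0 adjusted over all genes tested. The genes with the smallest p were Cxcl12, Nkd1, Rassf5 and Cst6, each with adjusted p = 0.153, and Traf1, with adjusted p = 0.164. Wwox had the value -1.73 (adjusted p = 0.525), or -0.043 without the library labelled DKO young 3 (adjusted p = 0.999). Trp53 had 3.20 (adjusted p = 0.347), or 0.60 without the library labelled DKO cSCC 3 and 4.68 without the library labelled DKO young 3 (adjusted p = 0.891 and 0.195). No gene was called by edgeR, with 2296 at an unadjusted p under 0.05, 461 by DESeq2 and 0 by voom. Leaving out PKO young 2 gave 11 calls, PKO cSCC 2 gave 3, and PKO cSCC 1 or DKO cSCC 2 gave 1 each. Calls ended for sebaceous and Wnt genes without PKO young 1 (adjusted p = 0.132 and 0.0712) and for stress, cell cycle, macrophage and muscle genes without PKO young 3 (0.0638, 0.0908, 0.128 and 0.166). Sebaceous genes lost theirs without DKO young 2 (0.0668) and cell cycle genes without PKO cSCC 2 or DKO cSCC 2 (0.205 and 0.0972). So did sebaceous, stress and macrophage genes without PKO cSCC 3 (0.0834, 0.0775 and 0.0562), and sebaceous, stress, macrophage and muscle genes without the library labelled DKO cSCC 3 (0.416, 0.105, 0.0573 and 0.0576).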

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

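The tests of keratinocyte share, of sex and of the labels and cells of the libraries labelled DKO young 3 and DKO cSCC 3 were chosen only after the levels had been seen, unlike the counts of other splits. Differences of Wwox effects were tested as interaction terms, and the lists below passed by camera with a preset correlation. With an estimated correlation none of them passed (adjusted p = 0.885 to 0.894 for the p53 background and 0.245 to 0.786 for tumours). Young epidermis labelled p53-deleted included PKO young 2 and 3 and the library labelled DKO young 3. Their Trp53 was 21.8, 19.2 and 21.1 CPM, against a mean of 34.4 CPM in WT young. The p53-intact side holds the WT young libraries, which were lower in basal keratinocyte genes and higher in erythrocyte markers than WKO. Between that epidermis and p53-intact young epidermis the median log2 difference was -1.39 for junction genes and -1.87 for basal keratinocyte genes. It was -1.92 for sebaceous genes, -0.653 for cell cycle genes and 3.86 for erythrocyte markers. Between tumours and young p53-deleted epidermis it was 2.73 for hair follicle, 1.86 for sebaceous, 0.408 for cell cycle, 0.591 for Wnt and 1.44 for Notch genes, and -1.29 for stress and wound and -0.938 for glycolysis genes. Among markers it was 1.4 for fibroblasts, 2.14 for macrophages, 5.37 for T cells, 5.56 for endothelial cells and 3.59 for muscle and adipocytes. No group had the 4 libraries that a test for an outlying library needs.

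For the p53-background and tissue differences the real count was 0 genes, which each of the 100 drawn splits of the libraries meets by construction, so the splits say nothing about chance there. The highest other counts were 1153 and 42. A split with 1153 genes points to a structure of the samples, and what it separates was not tested. Groups of 3 against 3 have 10 splits, too few for a share under 0.05. The real count and the highest of the other splits were 1 and 0 for DKO against PKO cSCC (1 split as large), 3563 and 0 for WKO against WT young (1 split), and 1 and 1 for PKO against WT young (2 splits). They were 4629 and 0 for DKO against WT young (1 split) and 0 and 1 for DKO against PKO young, where all 10 splits meet a count of 0 by construction.

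In the young knockout libraries other than PKO young 3, basal keratinocyte genes summed to 13600 to 23700 CPM against 3490 to 4430 CPM in young WT (4120 CPM in PKO young 3) and T cell markers to 44.8 to 951 CPM against 1780 to 2210 CPM, while sums of endothelial genes (212 to 222 CPM in DKO, 154 to 209 CPM in WT) and of fibroblast genes (up to 4160 CPM in the library labelled DKO young 3, at most 2560 CPM in WT) were not lower throughout. A lower share of keratinocytes in WT, as the whole cause, would move basal and differentiated genes together if other cells expressed neither list. In DKO the log2 ratio of differentiated to basal summed CPM was 0.506 ± 0.452 against -1.61 ± 0.638 in WT (SD, n = 3 each). This difference of 2.12 had no overlap, which chance gives in 10% of cases. Basal list genes expressed by other cells could lower the ratio in WT by themselves, which was not tested, so the ratio does not decide the question. It was also -1.86 in PKO young 1, where basal genes were high, and the DKO values include 0.14 in the library labelled DKO young 3. For WKO and PKO the differences of 1.07 and 0.662 did not clear the spread between libraries. A lower share of keratinocytes and a change within them thus cannot be told apart in WKO, PKO or DKO. For sex as the whole cause, WT young 2 and 3 had Xist at 418 and 359 CPM, like the knockouts (322 to 1550 CPM). They had at most 4430 CPM of basal genes, below each WKO and DKO library, which argues against sex alone there. WT young 2 also held Y-linked RNA, with Ddx3y at 4.08 and Eif2s3y at 1.84 CPM, so this rests mainly on WT young 3 (Ddx3y 0.113 CPM). For PKO as a group the test could not tell, since PKO young 3, with Xist at 322 CPM, had 4120 CPM of basal genes. PKO young 1 and 2, with Xist at 384 and 601 CPM, had at least 17300 CPM, but were picked after these levels were seen. An effect of the deletions stays open.

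The library labelled DKO young 3 had Wwox at 7.34 CPM and, among the pairs of libraries, lay closest to PKO young 2. A swap with a PKO young library would leave a PKO library low in Wwox, and the lowest was 7.65 CPM, which argues against it. The pair differed by a coefficient of biological variation of 0.119, under the lowest value of 0.21 for libraries of one group. Pairs of PKO young libraries differed by 0.519 to 0.63. RNA shared with PKO young 2, with a wrong label, would bring so low a value and may be the cause. A wrong label on RNA of another mouse, or cells without deletion, would leave the closeness of this pair unexplained. Both libraries were kept as separate replicates in the reported fits. Cells without deletion could also bring Wwox and Trp53, which stood at 21.1 CPM, but PKO young 2 had 21.8 CPM, so these explanations cannot be told apart by Trp53. Incomplete deletion in that mouse was not tested.

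The library labelled DKO cSCC 3 had Trp53 at 45.5 CPM and high differentiated keratinocyte genes. Cells with neither gene deleted, as the whole cause, would bring both genes, but Wwox was 20.1% of the young WT mean (95% Poisson limits 12.4% to 30.7%) and Trp53 132% (121% to 144%). A swap with a PKO cSCC library is argued against by the lowest Wwox among those, 7.36 CPM. A single wrong label on a sample with Trp53 intact and Wwox deleted may be the cause, since Trp53 lay within the range of WKO young libraries, 38.8 to 48.5 CPM. Those libraries had Xist at 399 to 871 CPM and Eif2s3y at 0, unlike this library, with 0.0892 and 23.8 CPM. Its closest library was WKO young 1, at a coefficient of biological variation of 0.5, against 0.538 for DKO cSCC 2, the closest tumour. Its Cdkn2a, given below, was also far under that of the other tumours. A tumour that kept Trp53 stays open and was not tested.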

How the results depend on the processing

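Added after seeing the data were the robust prior, the removals of pairs of libraries, the T cell marker score and an adjusted p under 0.1. The cause of the changes below was not tested. Called genes are given in the order DKO against PKO cSCC, PKO cSCC against old WT, DKO cSCC against old WT, WKO, PKO and DKO against WT young, DKO against PKO young, old against young WT, p53-background difference and tissue difference. The reported counts were 1, 2, 0, 3563, 1, 4629, 0, 351, 0 and 0. DESeq2 gave 235, 2587, 743, 5048, 2168, 5637, 177, 2049, 1103 and 461, voom with quality weights 0, 1, 1, 7304, 1883, 6752, 0, 102, 708 and 0, and no low-count filter 375, 2285, 853, 3257, 990, 3928, 0, 1068, 13 and 93. A replicate block gave 2, 0, 0, 2355, 1, 3590, 0, 0, 0 and 0, although the numbers do not pair the libraries, since the 57 same-number pairs had a median r of -0.0379 and 4 of 20 libraries lay closest to their own number. RLE gave 1, 2, 0, 3498, 3, 4632, 0, 400, 0 and 0, and TMMwsp 1, 59, 0, 3464, 3, 4572, 0, 317, 0 and 0, with a median shift of all genes of -0.103 (log2) for PKO cSCC against old WT. A robust prior gave 1, 2, 0, 3480, 1, 4585, 0, 364, 0 and 0. A minimum of 10 CPM gave 1, 326, 0, 2882, 447, 3675, 0, 441, 0 and 0, over fewer genes, with median shifts of -0.185, -0.108 and -0.127 for PKO cSCC against old WT and WKO and DKO against WT young. The test against a log2 change of 1 gave 1, 2, 0, 0, 1, 702, 0, 0, 0 and 0, and an adjusted p under 0.1 gave 1, 1956, 0, 5611, 1921, 6279, 0, 1434, 0 and 0. All 20 libraries in the fit gave 2, 3876, 788, 2199, 3, 3145, 0, 154 and 0 for the first 9, and only the groups compared 3, 1, 0, 4612, 0, 4811, 0 and 129 for the first 8. The tissue difference had 0 with only the 12 libraries of its groups. Against young WT the tumours had 5195 (PKO) and 2087 (DKO) genes, and against young epidermis of their genotype 2087 and 1326. The T cell marker score gave 0, 3, 1, 0, 0 and 0 for WKO, PKO, DKO, DKO against PKO young, old WT and the p53-background difference. That score was 5.57 to 5.96 (mean log2 CPM) in WT young and at most 4.15 in WKO, DKO and old WT, so the design fixed much of the loss of calls there, which says nothing about stability. Wwox in WKO then had a log2 change of -2.75 (adjusted p = 0.537). Without the libraries labelled DKO young 3 and PKO young 2, or DKO young 3 and PKO young 3, WKO had 3897 or 4701 genes, PKO 5 or 3046, DKO 4515 or 5157, DKO against PKO 693 or 2 and the p53-background difference 1 or 1018. With 1 library left out the counts ranged over 0 to 1, 0 to 67, 0 to 2, 893 to 3513, 1 to 2998, 1609 to 4045, 0 to 403, 0 to 434, 0 to 1199 and 0 to 11, where a lone old WT library is assumed to vary like the other groups. Called lists were 16, 15, 13, 18, 14, 18, 11, 15, 5 and 12. They came to 0 in each with an estimated correlation, and to 1, 4, 0, 12, 4, 10, 0, 2, 0 and 1 by fry. For the p53-background difference they were 9 with a block, 13 with no filter, 9 with all 20 libraries, 10 without DKO young 3 and PKO young 3, and 5 to 15 with 1 library left out. These values reversed, with the range over single libraries left out where that reversed it. Trp53 in DKO against PKO cSCC had a log2 change of -0.2016 without the library labelled DKO cSCC 3, and up to 2.853 without DKO cSCC 1. Wwox in PKO cSCC against old WT had 0.06141 without old WT 2 and -0.5413 without old WT 1. With the T cell marker score Wwox had 0.1953 in PKO against WT young, and Thy1 and Cfd had 0.1588 and 0.3713 in DKO against WT young. Trp53 in old against young WT had 0.1483 with a block, 0.09331 with that score, 0.02012 without old WT 2 and -0.4225 without old WT 1. As a signed -log10 of the adjusted p, cell cycle genes in DKO against PKO cSCC came to 0.274 without PKO cSCC 1 and -10.7 without PKO cSCC 2. In old against young WT, mesenchymal genes came to 0.27 and macrophage genes to 0.773 without old WT 1, and to -3.96 and -3.11 without old WT 2. Of the other values of called lists 1450 kept their side of the threshold and 382 did not, and of called named genes 3967 kept it and 1122 did not. Of values of named genes not called 816 stayed so and 169 passed. Depth limits genes near the floor of 3 counts over a group.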

Other observations

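Genes named here were chosen after their values were seen and were not tested as a group. Casein genes, which encode milk proteins, were highest in old WT 2, with 8500 CPM of Csn2, 7220 CPM of Csn1s1, 7380 CPM of Csn1s2a and 2200 CPM of Csn3. Old WT 1 had 43.2, 104, 9.76 and 29.6 CPM of them and WKO young 2 had 547, 366, 465 and 61.4 CPM. Csn2 was at most 0.169 CPM in WT young, 26.8 CPM in DKO young, 16.2 CPM in PKO young and 6.14 CPM in the tumours.

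Cdkn2a, which encodes the cell cycle inhibitors p16 and ARF, was 38.5, 57 and 59.2 CPM in PKO cSCC and 134 and 55.8 CPM in DKO cSCC 1 and 2, against 0.624 CPM in the library labelled DKO cSCC 3. Young and old epidermis had at most 2.91 CPM of it. Gpx2, a glutathione peroxidase, was 8.03 to 73 CPM in the 6 tumours and at most 1.91 CPM in epidermis. Col9a1, a cartilage collagen gene, was 97.6 CPM in PKO cSCC 2 and 0 in the other 5 tumours.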
